A study of Mus musculus with 6 samples.

How the data were processed

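Polyadenylated RNA of bEnd.3 cells was sequenced in 6 libraries, 3 of cells with a control mimic and 3 of cells with a miR-423-5p mimic, on an Illumina instrument with paired reads and a strand-marking (dUTP) preparation, per the labels' protocols. The deposited table holds, for 30768 genes, a whole-number read count and an FPKM value per library, per the file headers, together with gene ontology, KEGG and Reactome terms. Cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR and the build GRCm38 are named, with no role, per the submitters' processing notes. The annotation release, the counting settings and the strand setting are not given in the sources used here, so overlapping and antisense genes, and families of near-identical genes, are uncertain. The file headers do not say how the FPKM values were made. The ratio of count to FPKM differed between libraries by a near-constant factor over well-counted genes, as scaling for gene length and library size gives. The table holds no comparison of the authors' own, so none was set beside the results. The table lists no row without a gene.

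Total counts ran from 63217696 to 78456344 per library. At these totals a count of 0 allows up to 3 counts, or 0.0382 to 0.0475 CPM, for counting error only. No pair of libraries agreed within sampling noise in a chi-square test. Of the table's genes, 30669 are in the GENCODE M21 annotation of GRCm38 by identifier, and 27833 (90.5%) have the same chromosome, start and end there. Coordinates are those of the table.

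Before the data were examined, the test was set as limma on log2(FPKM + 1), or edgeR's quasi-likelihood test if the table held counts. It does, so the deposited counts were tested with edgeR 4.0.16 (R 4.3.3; filterByExpr, TMM scaling, estimateDisp, glmQLFit and glmQLFTest) on the group alone, leaving 18103 genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are counts scaled to the TMM-adjusted size of the library. The SE of a log2 fold change is its size over the square root of the F statistic. A fold against a group with all libraries at 0 was taken against 3 counts per library and is a lower bound.

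The 28 gene lists, the rule for named genes and the alternatives were also fixed before the data were examined. Named genes were the 12 largest increases and 12 largest decreases among called genes with 5 FPKM or more in the higher group, no overlap between the groups' libraries and no clone-type or pseudogene symbol; up to 4 members per list by smallest p; 10 genes with an 8mer site and a decrease, by smallest p; Mir423 and Nsrp1; and up to 3 called genes per enriched term. Some of the genes that these rules select are not reported here. Lists with 5 or more tested members, 24 in all, were tested with camera (limma 3.58.1, preset correlation of 0.01), with an estimated correlation and with fry as alternatives. Of a gene symbol on several rows, a list used the row with most counts. Terms of 10 to 500 tested genes were tested with one-sided Fisher's exact tests against the 13701 tested genes with any term.

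Seed sites were searched in the longest annotated 3' UTR of each gene, made from the coding and exon coordinates of GENCODE M21. The site label was shuffled 100000 times over genes within 5 bins of 3' UTR length by 5 of GC, and the difference in medians was given a 95% bootstrap interval from 2000 resamples. Principal components used log2 CPM with a prior count of 2.

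The steps were tested on simulated data. In counts drawn for this comparison from the means of these libraries, with 200 genes changed, 52.1% of 2-fold and 82.7% of 4-fold changes were recovered among 17601 genes tested, and 7.09% of calls were false. With no change simulated, 0 of 17620 genes were called. The seed test on 13863 genes gave a permutation p of 0.792 for a trend with base composition and no site effect, and an adjusted difference of -0.080 for a simulated effect of -0.1.

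Alternatives were DESeq2 1.42.0, DESeq2 size factors, no filter, leaving out each library, a block on the replicate number, a fold limit of 1.5 and limma on FPKM with pseudocounts of 0.1, 1 and 5, other filters, scalings and weights. Those chosen after seeing the data were edgeR with robust dispersion, edgeR scaled to total counts, terms without control 3, and seed tests with DESeq2 and total-count fold changes. Scripts ran on Python 3.11.15 with scipy 1.17.1.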

Results

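Messenger RNA was measured by sequencing in bEnd.3 cells, a mouse brain endothelial line, given either a control mimic or a mimic of the microRNA miR-423-5p. A mimic is a short synthetic RNA that acts as the mature microRNA, which pairs through its seed with messenger RNAs and lowers them. The 6 libraries fall into 2 groups of 3. Total counts were 64561989, 69250575 and 68873482 in controls 1, 2 and 3 and 74461585, 78456344 and 63217696 in miR-423-5p libraries 1, 2 and 3. The labels do not say whether the libraries of a group came from separate cultures. The p-values of single genes measure the spread between these libraries, which may therefore be technical. Permutation tests of seed sites, Fisher's exact tests and bootstrap intervals take genes as their units. They do not measure the spread between libraries. More genes had a count in the control libraries (24433 ± 779, SD, n = 3) than in the miR-423-5p libraries (22883 ± 302, SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). Across genes, log2(FPKM + 1) correlated with a mean Pearson r of 0.986 within groups and 0.969 between groups. The first principal component, with 44.3% of the variance, separated the groups, and the second, with 19.2%, set control 3 (-56.3) apart from controls 1 (43.3) and 2 (39.9).

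The comparison of miR-423-5p with control cells asks how overexpression of the microRNA changes endothelial gene expression. The largest changes are given among called genes with 5 FPKM or more in the higher group, no overlap between the groups' libraries and no clone-type or pseudogene symbol. Of those that rose most in the miR-423-5p cells, Csf3, which encodes the granulocyte growth factor G-CSF, rose 9.51-fold. It went from 1.54 ± 0.467 to 14.6 ± 1.04 CPM, which are counts scaled to the size of the library (SD, n = 3). The hyaluronan receptor gene Lyve1 rose 3.36-fold, the Notch receptor gene Notch4 3.19-fold, the semaphorin receptor gene Plxnd1 3.18-fold and the flow-responsive transcription factor gene Klf2 3.17-fold. Within the same limits, the genes that fell most included the fibrillar collagen gene Col1a1, 11.7-fold lower, and the chemokine genes Ccl4 and Cxcl10, 3.40-fold and 3.13-fold lower. The macrophage growth factor gene Csf1, 2.64-fold lower, and the cyclin E gene Ccne1, 2.61-fold lower, were also among them.

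Of 18103 genes tested with edgeR's quasi-likelihood test, 1646 rose and 1305 fell at a Benjamini-Hochberg adjusted p under 0.05, of which 280 and 419 changed by 2-fold or more. The libraries of the groups did not overlap for 6946 of the tested genes, where chance gives 10%. With libraries scaled to total counts only, an alternative chosen after seeing the data, 874 rose and 2569 fell, so that the share of calls that rose was 25.4% in place of 55.8%. That scaling moved the median log2 fold change of all genes from -0.02 to -0.18, and changes are given relative to the main scaling. The count of called genes, 2951 with all libraries, was 1162 without control 1, 942 without control 2, 1514 without miR-423-5p 1 and 1230 without miR-423-5p 3. Without miR-423-5p 2 the count rose to 4222. That library had a Pearson r of 0.983 with miR-423-5p 1 and with miR-423-5p 3, which had 0.992 with each other. Without control 3, which stood apart, 2018 genes were called, and 868 of them fell.

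Within the limits on level, overlap and symbol, the other genes with the largest increases included Rasip1, which encodes a Ras-binding protein of endothelial cells (3.60-fold), the integrin beta 3 gene Itgb3 (3.50-fold), the organic anion transporter gene Slco4a1 (3.48-fold) and the retinal reductase gene Dhrs3 (4.02-fold). Itgb3 went from 39.7 ± 4.65 to 139 ± 15.4 CPM and Slco4a1 from 53.7 ± 7.54 to 187 ± 7.62 CPM (SD, n = 3). Psg22 (8.15-fold), Stfa3 (6.2-fold) and Pbp2 (3.70-fold) also rose, and they belong to families of similar genes among which reads can be shared, so their values are uncertain. The other genes with the largest decreases within those limits were the BMP-induced regulator gene Id3 (5.40-fold lower), the kinase gene Sbk1 (3.21-fold), the acyl-CoA synthetase gene Acsf2 (3.15-fold), the E2F partner gene Tfdp1 (2.59-fold), the transcription factor gene Snai2 (2.57-fold), the interferon-induced GTPase gene Gbp5 (2.52-fold) and the spindle protein gene Psrc1 (2.51-fold). Some genes outside those limits fell by more, such as Col6a2, Col3a1 and Cspg4. Csf1 fell from 738 ± 26.2 to 279 ± 8.64 CPM, a log2 fold change of -1.40 ± 0.074 (SE; edgeR adjusted p = 0.000457). Col1a1 fell from 44.6 ± 18.1 to 3.79 ± 0.867 CPM, a log2 fold change of -3.55 ± 0.35 (SE; edgeR adjusted p = 0.00137).

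**Figure D1:**
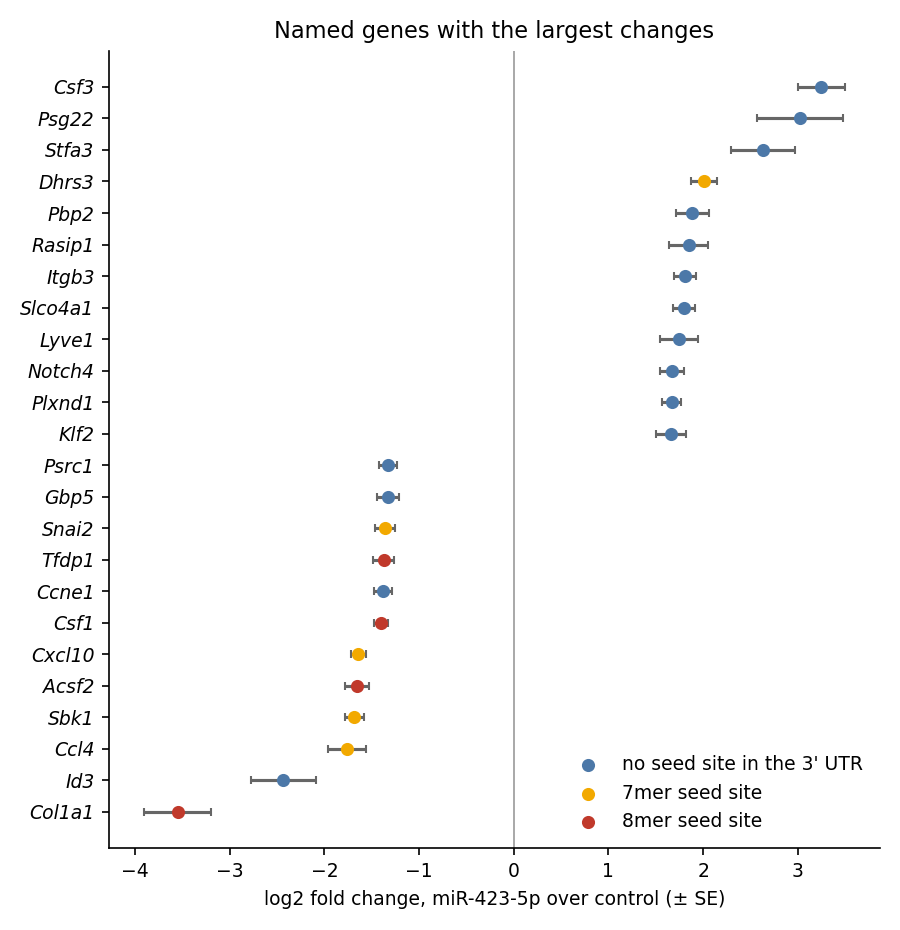
Log2 fold change of miR-423-5p over control cells (x axis) for the 12 genes with the largest increases and the 12 with the largest decreases under the naming rule, with SE bars (n = 3 per group) and colour by the best miR-423-5p seed site in the 3' UTR. Of the 12 genes that fell, 8 had a seed site, and of the 12 that rose, 1 did.

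Genes that mark endothelial cells rose as a group: of 19 tested, 13 rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 1.9e-14, and 0.0473 with an estimated correlation). The nitric oxide synthase gene Nos3 rose 2.30-fold, from 861 ± 78.7 to 1979 ± 70.1 CPM (SD, n = 3; edgeR adjusted p = 0.000815). Pecam1, an adhesion molecule of endothelial junctions, rose 2.03-fold and the receptor kinase gene Tie1 1.92-fold, while the adhesion molecule gene Mcam fell 2.38-fold. Without control 2, which lowered the count most, 9 of the list rose and 1 fell. Of 7 tested fibroblast and pericyte markers, 2 fell between the same groups and 5 were not called. That marker list was called by camera (adjusted p = 0.0214), and not with an estimated correlation (adjusted p = 0.423). Whether the mix of cells differed was not settled. Of 17 genes of angiogenesis and Notch signalling, 4 rose and 1 fell (5 and 2 adjusted over the list alone), with Plxnd1, the Notch ligand gene Dll4 (6.11-fold, from 0.966 ± 0.369 to 5.92 ± 0.679 CPM), Angpt2 (1.51-fold) and the chemokine receptor gene Cxcr4 (2.39-fold) among those that rose. The list was called by camera (adjusted p = 0.00167), and not with an estimated correlation (adjusted p = 0.423). Of 17 blood-brain barrier genes, 1 rose and 3 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.312). The amino acid transporter genes Slc7a5 and Slc3a2 fell 1.78-fold and 1.32-fold, and the efflux pump gene Abcb1a fell 1.54-fold. The number that fell was 1 without control 1, control 2 or miR-423-5p 3 and 5 with total-count scaling, and 2 rose without control 1 or miR-423-5p 2.

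Genes of cholesterol synthesis rose as a group: 12 of 16 rose and none fell (15 and 0 adjusted over the list alone; camera adjusted p = 4.0e-13, and 0.0473 with an estimated correlation). The farnesyl diphosphate synthase gene Fdps rose 2.61-fold and the squalene epoxidase gene Sqle 1.84-fold. Without control 2, 6 of the 16 rose. Of 20 genes of hypoxia and glycolysis, 11 rose and 1 fell (14 and 2 adjusted over the list alone; camera adjusted p = 9.0e-07, and adjusted p = 0.264 with an estimated correlation). Pkm, the pyruvate kinase gene, rose 1.64-fold, Egln3 2.11-fold and Pgk1 1.44-fold, while the stress gene Ddit4 fell 1.81-fold. The number that rose was 2 without control 2, 7 without miR-423-5p 1 and 6 without miR-423-5p 3. Of 20 oxidative phosphorylation genes 2 rose, among them Sdha, and none fell (0 and 0 adjusted over the list alone), and of 20 ribosomal protein genes 3 rose, Rps4x, Rps2 and Rpl7, and none fell (5 and 0 adjusted over the list alone). Both lists were called by camera (adjusted p = 0.00123 and 0.000125), and neither with an estimated correlation (adjusted p = 0.447 and 0.503). With total-count scaling 0 and 1 of them rose, without miR-423-5p 2 the numbers were 12 and 16, without control 3 they were 1 and 2, and 0 rose in either list with edgeR when any other single library was left out.

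Interferon-stimulated genes fell as a group: of 22 tested, 14 fell and none rose (17 and 0 adjusted over the list alone; camera adjusted p = 6.7e-12, and adjusted p = 0.0622 with an estimated correlation). Cmpk2 fell 2.38-fold, from 447 ± 54.5 to 188 ± 24.7 CPM (SD, n = 3), the antiviral GTPase gene Mx2 2.01-fold, Ifit1 1.77-fold and Gbp2 1.63-fold. The number that fell was 7 without control 1, control 2 or miR-423-5p 3, 8 without miR-423-5p 1 and 10 without control 3. Without miR-423-5p 2, 15 fell and 1 rose. Targets of p53, the transcription factor of the DNA damage response, fell too: 13 of 19 fell and none rose (13 and 0 adjusted over the list alone; camera adjusted p = 6.7e-12, and 0.0386 with an estimated correlation). Sesn2 fell 2.08-fold, Zmat3 1.72-fold, the cyclin-dependent kinase inhibitor gene Cdkn1a 1.71-fold and Gtse1 1.58-fold. Without control 1, 7 fell. Of 20 genes of endothelial activation and NF-kB signalling, 6 fell and 3 rose (9 and 5 adjusted over the list alone; camera adjusted p = 0.00103, and adjusted p = 0.264 with an estimated correlation). Cxcl10, Csf1, the NF-kB inhibitor gene Tnfaip3 (2.14-fold) and the P-selectin gene Selp (1.35-fold) were among those that fell. Without miR-423-5p 3, 3 fell and 1 rose, without control 1 or control 2, 5 fell and 1 rose, and with total-count scaling 9 fell and 2 rose.

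Of 22 genes of S phase and DNA replication, 8 fell and none rose (13 and 0 adjusted over the list alone; camera adjusted p = 8.3e-07, and 0.0473 with an estimated correlation). Besides Ccne1, the histone mRNA binding protein gene Slbp fell 2.09-fold, Ccne2 2.03-fold and the replication licensing gene Cdc6 1.48-fold. Of 22 genes of mitosis, 7 fell and none rose (10 and 0 adjusted over the list alone; camera adjusted p = 0.000648, and adjusted p = 0.0622 with an estimated correlation), with Cenpf 1.46-fold, Kif11 1.34-fold, Aurkb 1.32-fold and Cenpe 1.30-fold lower. The mitosis count was 1 without control 3, 2 without miR-423-5p 1 and 0 without control 1, control 2 or miR-423-5p 3. The S-phase count was 3 without control 1, control 2 or miR-423-5p 3 and 5 without control 3 or miR-423-5p 1, and total-count scaling gave 18 and 15 in S phase and mitosis. Of 16 targets of TGF-beta and BMP, 7 fell and 1 rose (9 and 2 adjusted over the list alone; camera adjusted p = 0.00123, and adjusted p = 0.225 with an estimated correlation). Besides Id3, the matricellular protein gene Ccn2 fell 1.94-fold and Atoh8 3.07-fold, and the ligand gene Tgfb1 rose 1.56-fold. The number that fell was 3 without control 1 or miR-423-5p 3, 2 without control 2 and 4 without miR-423-5p 1.

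**Figure D2:**
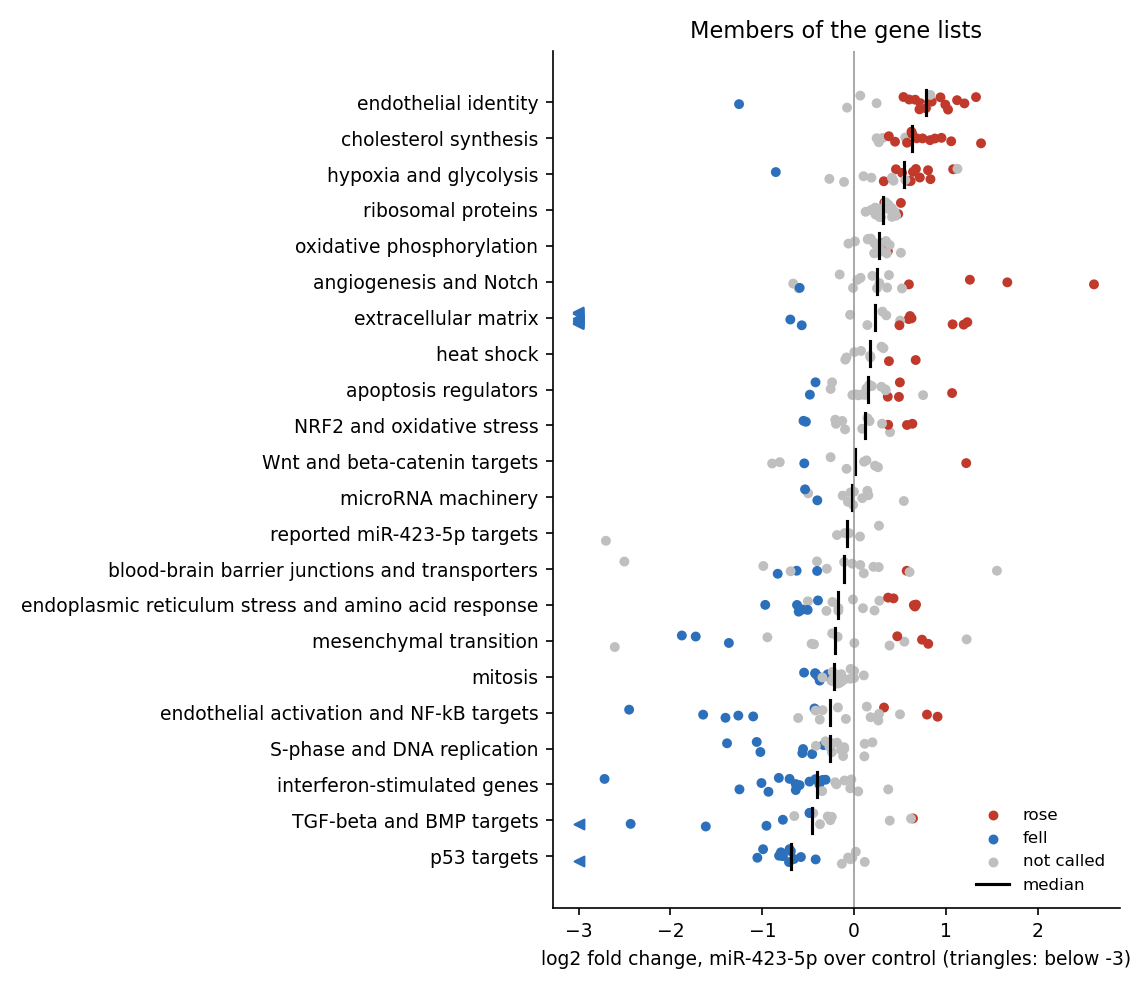
Log2 fold change of miR-423-5p over control cells (x axis) for each tested member of the gene lists other than cell type markers (y axis), with members that rose, fell or were not called in colours and the median of each list as a bar; triangles mark members below -3. The medians of these lists run from -0.69 in p53 targets to 0.78 in endothelial identity.

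Extracellular matrix genes moved apart: of 20, 7 rose and 8 fell (10 and 8 adjusted over the list alone; camera adjusted p = 0.521), and the median log2 fold change was 0.23 while the mean was -1.15. Sparc rose 2.1-fold and the laminin gene Lama4 2.35-fold, while the collagen genes Col6a2, Col3a1 and Col1a1 fell 30.1-fold, 16.7-fold and 11.7-fold. Without control 1, 5 of the list fell, and without control 2, 4 fell. In control 3, Col1a1, Col1a2, Col3a1, Col5a2, Col6a2, Lox, Lum and Dcn stood at 0.319 to 0.444 of their mean in controls 1 and 2. Of 16 genes of mesenchymal transition, 3 rose and 3 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.408), with Vim 1.75-fold higher and Snai2, Acta2 (3.67-fold) and Mmp2 (3.31-fold) lower. Of these genes 1 rose without control 1, control 2 or miR-423-5p 1, 5 fell without miR-423-5p 2 or miR-423-5p 3, and 1 rose and 5 fell with total-count scaling. Of 20 genes of endoplasmic reticulum stress and amino acid response, 5 rose and 6 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.389): the chaperone gene Calr rose 1.59-fold and Xbp1 1.57-fold, while Chac1 fell 1.96-fold and Atf3 1.52-fold. The numbers were 3 and 2 without control 1 or miR-423-5p 3, 3 and 3 without control 2 and 3 and 9 with total-count scaling. Of 20 apoptosis regulators, 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.134), with the BIM gene Bcl2l11 2.09-fold higher. Of 14 NRF2 genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.465), with Nqo1 1.55-fold higher and the heme oxygenase gene Hmox1 1.47-fold lower. With total-count scaling 2 apoptosis regulators rose and 4 fell, and 2 NRF2 genes rose and 3 fell. Of the NRF2 genes 1 rose and 1 fell without control 1, 6 rose without miR-423-5p 2, none fell with edgeR without miR-423-5p 3, and 1 fell without control 2, control 3 or miR-423-5p 1. Of the apoptosis regulators 1 rose and none fell without control 1, control 2 or miR-423-5p 3, and 2 rose without miR-423-5p 1. Of 10 heat shock genes, 2 rose and none fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.079), with Hspb1 1.59-fold higher. None was called with edgeR without control 1 or control 2, where 2 and 4 had an unadjusted p under 0.05, and 1 rose without miR-423-5p 1 or miR-423-5p 3 and with total-count scaling. Of 10 Wnt targets 1 rose, the cyclin D1 gene Ccnd1 at 2.33-fold, and 1 fell, Znrf3 at 1.46-fold (1 and 1 adjusted over the list alone; camera adjusted p = 0.203). Of 12 genes of the microRNA machinery 2 fell, Xpo5 1.45-fold and Dgcr8 1.32-fold, and none rose (2 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.457). With any single library but miR-423-5p 2 left out, 1 gene of the microRNA machinery and no Wnt target fell with edgeR.

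Markers of other cell types differed between libraries. Of 7 tested pericyte and fibroblast markers, 2 fell, Cspg4 at 6.33-fold and the proteoglycan gene Lum at 49.9-fold, and none rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.0214, and adjusted p = 0.423 with an estimated correlation). Of 6 astrocyte markers, 1 fell and none rose (1 and 0 adjusted over the list alone; camera adjusted p = 0.0633): Sox9 was at 1.36 ± 0.315 CPM in the controls and at 0 counts in the 3 miR-423-5p libraries, at least 30.7-fold lower against a floor of 3 counts per library. Of 3 tested macrophage markers none was called with edgeR on all libraries (1 rose and 2 fell adjusted over the list alone, 3 at an unadjusted p under 0.05), 1 rose with a block on the replicate number or without miR-423-5p 2, and DESeq2 called 2 of 10, 1 in each direction. Csf1r stood at 21.8 CPM in control 3 and between 0.905 and 1.61 CPM in the other libraries, and Itgam at 12.1 CPM against at most 0.186 CPM. Of 3 tested neuron markers, 1 rose, the neurofilament gene Nefl at 3.15-fold, and none fell (1 rose and 2 fell adjusted over the list alone). Tubb3 stood at 24.5 CPM in control 3 and at most 0.554 CPM elsewhere, and Syp at 8.99 against at most 0.48 CPM. Of 4 epithelial markers none was called with edgeR (0 adjusted over the list alone, 0 at an unadjusted p under 0.05) or DESeq2, 1 fell without control 2, and of 4 lymphatic markers Lyve1 and Flt4 rose and none fell (2 and 0 adjusted over the list alone), Flt4 by 1.28-fold. Of the lymphatic markers 1 rose without control 1, control 2 or miR-423-5p 3, and 3 rose without control 3. Of the pericyte and fibroblast markers 1 fell without control 1, control 2 or miR-423-5p 1, and 3 fell without control 3 or miR-423-5p 3. With total-count scaling 4 fell, and with DESeq2 4 of 10 fell.

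**Figure D3:**
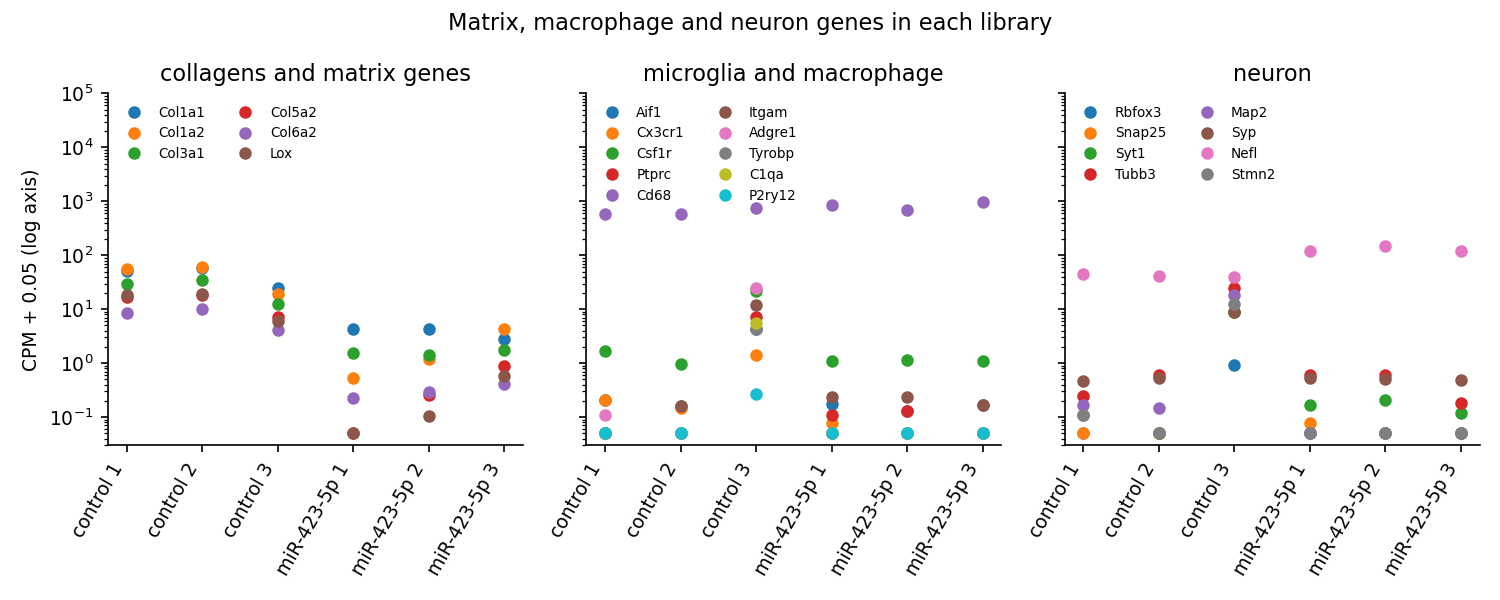
CPM plus 0.05 (log y axis) in each of the 6 libraries for 6 collagen and matrix genes, macrophage markers and neuron markers, with one point per gene and library. The matrix genes were high in the 3 controls, and neuron and macrophage markers other than Nefl and Cd68 were highest in control 3, as for Tubb3 at 24.5 CPM.

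Genes with a match to the miR-423-5p seed in the 3' UTR were lower in the miR-423-5p cells. The match to the seed (bases 2 to 8 of TGAGGGGCAGAGAGCGAGACTTT) is GCCCCTC, and GCCCCTCA is the 8mer. Among 13863 tested genes with an annotated 3' UTR, the 2754 with a site had a median log2 fold change of -0.08 and the 11109 without one 0.0019, a difference of -0.084 (95% bootstrap interval -0.105 to -0.058; two-sided permutation p = 1e-05 within strata of 3' UTR length and GC, the smallest that 100000 shuffles can give). For the 512 genes with an 8mer the difference was -0.167, and 656 genes with 2 or more sites had a median of -0.15. Of genes with an 8mer 20.3% fell, against 7.93% of the others. Of the 1163 genes that fell and have a 3' UTR, 32.2% had a site, against 19.9% of all genes (Fisher's exact p = 2.7e-25), and of the 1555 that rose 19.8% had one (Fisher's exact p = 0.973). GCCCCTC ranked 1 among the 42 orderings of its bases. Genes with the match in the coding sequence differed by -0.075, or -0.082 less the mean of the shuffles (permutation p = 1e-05). On that measure the 3' UTR difference was -0.074. The strata were those of the 3' UTR, so the length and composition of the coding sequence were not held constant. For the opposite arm, miR-423-3p, the difference was -0.024 (permutation p = 0.953). Without control 3 the difference for miR-423-5p was -0.054 (permutation p = 1e-05).

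Among genes with an 8mer site, Csf1 (chromosome 3, 107741048 to 107760469) had 4 sites in a 3' UTR of 2111 bases. Acsf2 had 7 sites in 1205 bases. Others with an 8mer that fell were the zinc finger gene Zfp553 (2.28-fold lower), the E2F partner gene Tfdp1 (2.59-fold), the RNA-binding protein gene Rbm38 (2.5-fold), the mitochondrial carrier gene Slc25a44 (2.19-fold), the sulfotransferase gene Chst14 (2.16-fold), Enc1 (2.07-fold), the HDL receptor gene Scarb1 (1.91-fold) and the ubiquitin ligase gene Rnf169 (1.82-fold). None of 6 tested genes reported elsewhere as miR-423-5p targets was called with edgeR (0 adjusted over the list alone, 0 at an unadjusted p under 0.05; camera adjusted p = 0.842) or DESeq2, limma called 1 of 5, and 0 of 5 with TMM scaling of FPKM. Cadm1, Ogt, Fam3a and Ing4 had log2 fold changes of -2.70 ± 1.31, 0.27 ± 0.14, -0.19 ± 0.13 and -0.10 ± 0.13 (SE), and that of Cadm1 was 0.40 without control 3. Nsrp1, the neighbour of the microRNA gene Mir423, had a log2 fold change of -0.32 ± 0.12 (SE; edgeR adjusted p = 0.1). Mir423 had too few counts to test, and a mimic is not read by sequencing of poly(A) RNA.

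**Figure D4:**
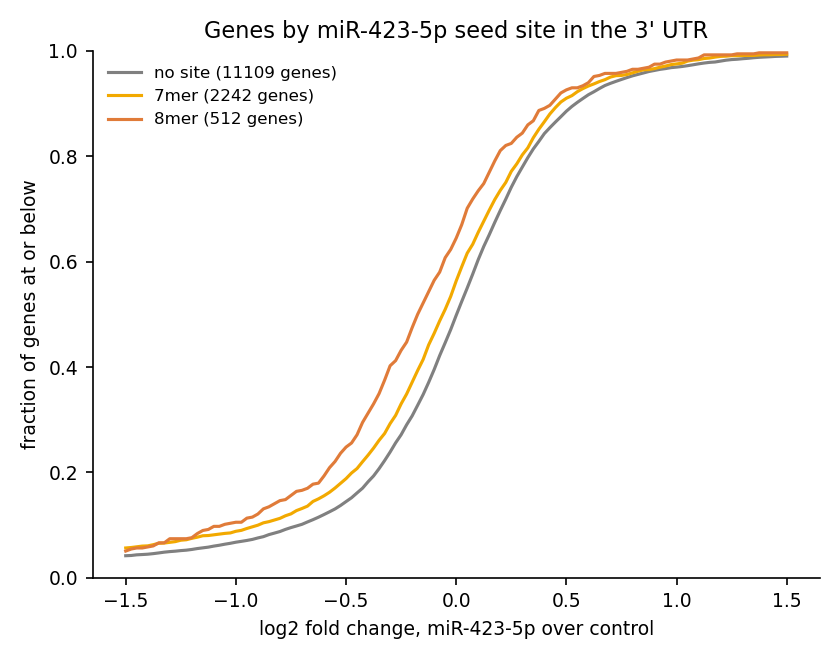
Cumulative fraction of genes (y axis) by log2 fold change of miR-423-5p over control cells (x axis), for genes with no seed site, with a 7mer and with an 8mer of miR-423-5p in the 3' UTR. The curve of the 512 genes with an 8mer lies to the left of that of the 11109 genes with no site.

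Gene ontology, KEGG and Reactome terms, as the deposited table pairs them with genes, were tested for enrichment among called genes with one-sided Fisher's exact tests. Of 3380 terms, 44 were enriched among genes that fell. Response to interferon-beta had 19 of 36 genes fall (adjusted p = 1.9e-08), among them the GTPase genes Tgtp1, 2.05-fold lower, and Igtp, 1.64-fold lower. Collagen-containing extracellular matrix had 43 of 175 fall (adjusted p = 1.0e-07), and 42 of its 175 rose (adjusted p = 0.000148). The p53 signalling pathway had 18 of 65 fall (adjusted p = 0.000687), with Gadd45a, a DNA damage response gene, 2.08-fold lower. Metaphase plate congression had 8 of 12 fall (adjusted p = 0.000198), with Incenp and Kif2c 1.37-fold and 1.28-fold lower. Among genes that rose 153 terms were enriched, and with total-count scaling the numbers were 81 among genes that rose and 129 among genes that fell.

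The smallest p of all genes was that of Gm45717 (chromosome 7, 140949222 to 140955937), singled out after its values were seen: it fell from 59.2 ± 9.79 to 1.32 ± 0.188 CPM (SD, n = 3; edgeR adjusted p = 5.5e-05). It overlaps the interferon-induced gene Ifitm2 (140954837 to 140955987) on the same strand, which rose 1.84-fold, so the split of reads between the pair is uncertain.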

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

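Robust dispersion, total-count scaling, terms without control 3 and seed tests with DESeq2 fold changes were chosen after seeing the data. The seed difference kept its sign and stayed past the threshold in each alternative for miR-423-5p, and for the opposite arm it was -0.024; the cause was not tested. Genes called numbered 1852 with no filter (1093 rose, 759 fell) and 1528 with a fold of at least 1.5 (769 and 759). They numbered 942 to 4222 with single libraries left out (570 to 2386 rose, 372 to 1836 fell), where fewer samples enter. The only number above that with all libraries, 4222, was without miR-423-5p 2. Total-count scaling gave 874 that rose and 2569 that fell. On FPKM, limma gave 784 and 2301 at a pseudocount of 1, 778 and 2263 at 0.1, 783 and 2307 at 5, 782 and 2316 without trend, 640 that rose with 5 FPKM in 3 libraries, 478 that rose of 1886 with no filter, and 6776 with library weights, of which 5016 fell. With TMM scaling of FPKM the numbers were 1426 and 1349, with median centring 1497 and 1141 and with quantile normalization 1177 and 1356, so the excess of falls depends on the scaling. Numbers of terms were 35 among genes that rose with the 500 smallest p, and 81 and 129 with total-count scaling. With an estimated correlation 4 of the 13 called lists remained called. With fry, oxidative phosphorylation (fry adjusted p = 0.0625) and ribosomal proteins (0.104) were no longer called. Fry also called lists that camera did not: heat shock (fry adjusted p = 0.013), apoptosis regulators (0.0343), NRF2 (0.045) and astrocyte markers (0.04755). Between groups r was 0.956 at 5 FPKM or more.

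The replicate numbers gave no clear pairing of the samples: same-numbered libraries deviated together with correlations of 0.075, -0.026 and 0.050. Control 1 correlated best with its own number, and controls 2 and 3 with another, control 3 only by 0.0515 against 0.0498. The labels do not say what the numbers mark, so pairing is not excluded. With the replicate block edgeR called 2411 genes, and limma 736 that rose and 2045 that fell. The block turned the camera direction of the extracellular matrix list, which was not called (median 0.22, adjusted p = 0.687), and the sign of Reln (0.13).

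Leaving out single libraries turned other values that were not called with all libraries. The camera direction of the matrix list turned without control 3, while its median stayed positive (0.17 to 0.30), and that of the reported targets turned without control 3, miR-423-5p 2 or miR-423-5p 3 (medians -0.15 to 0.0034, still negative at -0.011 and -0.035 in the latter 2). Log2 fold changes turned without control 3 for Cadm1 (-3.26 to 0.40), Itgam (-5.20 to 1.53), Tubb3 (-4.90 to 0.16), Syp (-3.37 to 2.7e-05), Krt8 (-2.54 to 1.15) and Reln (-1.30 to 1.16), and without miR-423-5p 2 for Ing4 (-0.19 to 0.033) and Pdpn (-0.16 to 0.012). For Itgam, Tubb3, Syp, Krt8 and Reln the negative value with all libraries came from control 3, where each stood highest. Krt8 was at 6.41 CPM there against at most 0.730 CPM elsewhere, and Reln at 6.79 against at most 1.62 CPM. The cause of the other turns was not tested. Of 105 named genes that were called, none changed sign in an alternative run, and 79 to 105 stayed called with a single library left out. In counts simulated from the means of these libraries, 52.1% of 2-fold changes were recovered, so smaller changes are often missed.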

Other observations

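Genes of the lysosome and of the secretory pathway rose in the miR-423-5p cells. Of 112 KEGG lysosome genes 43 rose (one-sided Fisher's exact adjusted p = 7.6e-11): Arsa, which encodes arylsulfatase A, rose 1.78-fold, from 212 ± 10.1 to 376 ± 17.4 CPM (SD, n = 3), the mannosidase gene Manba 1.68-fold and the galactosidase gene Glb1 1.51-fold. Of 234 genes of N-linked glycosylation 59 rose (adjusted p = 5.5e-07), with the retrieval receptor gene Kdelr2 2.08-fold and Alg14 1.80-fold higher. Of 154 genes of protein processing in the endoplasmic reticulum 43 rose (adjusted p = 3.5e-06), with the disulfide isomerase gene P4hb 1.58-fold higher. Sphingolipid metabolism had 24 of 72 genes rise (adjusted p = 8.9e-05), with the sphingosine 1-phosphate exporter gene Spns2 2.90-fold and the desaturase gene Degs1 1.76-fold higher. Neutrophil degranulation, a Reactome term that holds many lysosomal and granule genes, had 115 of 396 rise (adjusted p = 9.3e-20), with the gelsolin gene Gsn 1.72-fold and the urokinase receptor gene Plaur 1.76-fold higher.

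The tests of word orderings and of chance among words for AGTACAA, of library depth, of all detected fibroblast genes, of fibroblast and reference genes without a seed match and of other splits of the libraries were chosen after the results were seen. The 0.1 CPM minimum and the 8 reference genes used with the held-out lists were not part of the predictions and were set when the tests were run.

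Genes with the word AGTACAA in the 3' UTR were higher in the miR-423-5p libraries than shuffles within strata of 3' UTR length and GC give. A candidate explanation is a control mimic with the sequence of cel-miR-239b-5p, a worm microRNA used for that purpose, whose seed pairs with this word, so that its targets would be lower in the controls; the labels do not name the control sequence. Genes with the 8mer AGTACAAA differed from the others by 0.110 on the log2 scale (95% bootstrap interval 0.056 to 0.147), or 0.158 less the mean of the shuffles, those with only a 7mer by -0.0048 (-0.031 to 0.020), or 0.043, and those with the word in the coding sequence by -0.0053, or 0.012 (permutation p = 0.289). Genes with AGTACAA differed by 0.065 and those with the other 209 orderings of its bases by -0.053 in the median (SD 0.018 over orderings). AGTACAA scored highest of 16113 words searched in these same fold changes. Its place above its orderings was therefore in part fixed in advance, and base composition or length is not decided by it. Of 100 shuffles of the fold changes 0 gave a word score as high, which argues against chance among the words searched. An effect of the control mimic stays open as a hypothesis, and among genes with no such word the miR-423-5p site difference was -0.091, or -0.083 less the mean of the shuffles.

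Fibroblast-type collagens and matrix genes were lower in the miR-423-5p libraries, which may come from fibroblast-type cells mixed into the control cultures. Of 35 held-out fibroblast genes, 17 were detected and under 2 CPM in the miR-423-5p libraries, with a median 3.08-fold lower (95% bootstrap interval 1.25 to 5.06), but that limit itself favours genes that fell, and the median of all 32 detected was 1.45-fold lower (0.975 to 3.22), with 20 lower, such as Bgn (19.9 and 4.70 CPM), and others level or higher, such as Aebp1 (411 and 473 CPM). In control 3 the 17 stood at 0.595 of controls 1 and 2, outside the 0.319 to 0.444 of the named genes, and with held-out genes both lower and higher, mixed cells cannot be told apart from a change in the endothelial cells. Seed sites were in 25% of 24 of these genes (95% exact interval 9.77 to 46.7), against 19.9% of all genes. Of 40 named and detected held-out genes, the 14 with no match in a 3' UTR or the coding sequence were 3.01-fold lower in the median (0.960 to 16.7), which decides nothing. Of the 8 reference genes, 5 had no such match (Col3a1, Col5a2, Lox, Lum and Dcn). They were 40.5-fold lower in the median (5.93 to 75), and 4 of the 5 were called. The reference genes define the pattern, so a fall among them was fixed in advance and that fold is no test. Those 5 hold none of the seed matches searched in an annotated 3' UTR or the coding sequence. The search did not cover shorter matches or other parts of the transcript. Direct seed pairing therefore stays open for them as for the others. A lower depth is excluded, as the miR-423-5p libraries held 1.07 times the counts of the controls.

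Neuron and macrophage transcripts stood out in control 3, where 197 genes were 4-fold or more above every other library. Some astrocyte and epithelial markers stood out there as well. Slc1a2 was at 7.17 CPM against at most 0.644 CPM elsewhere and Krt18 at 6.54 against at most 0.0884 CPM, while Gja1 and Krt19 were not raised. A candidate explanation is RNA or cells of neurons, macrophages and perhaps other types in that library alone. In the median, the 25 held-out neuron genes were 9.47-fold (95% bootstrap interval 3.78 to 15.7) above the mean of the other 5 libraries. The 25 held-out macrophage genes were 19.8-fold (6.34 to 76.1) above it. Ctss stood at 49.3 CPM in control 3 against at most 0.147 CPM elsewhere, and Dcx at 15.7 CPM against 0. In each list 22 of the 25 genes were higher in control 3, by 4-fold or more for 16 neuron and 18 macrophage genes. Some abundant members were level or lower there, such as Lgals3 (172 CPM, 0.991 of the mean of the other 5) and Crmp1 (223 CPM, 0.925). A greater depth is excluded, as control 3 held 0.984 of the mean total of the other 5, and no biological explanation was tested, since the labels give control 3 no condition of its own.

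The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 2951 genes and the highest of the others 1, so only the real split itself, 1 of the 10, reached that number.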
